A study of Mus musculus with 4 samples.

How the data were processed

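RNA from whole liver slices of 4 male mice, 2 AB6F1 and 2 B6AF1, was extracted with Trizol and hybridised to Affymetrix expression arrays as biotin-labelled cRNA, per the labels' protocols. The values used are the deposited intensity of each probe set, a linear MAS5 signal per the submitters' processing notes, which give no version of the tool. From the values themselves, each array had been scaled so that its mean, after the lowest and highest 2% of probe sets are dropped, was 500. Such scaling fixes the overall brightness of each array, so a change shared by all transcripts would not be seen. MAS5 combines perfect-match and mismatch probes, and its log ratios are noisy for dim probe sets. Scanner files and detection calls were not used here. Any genome build behind the annotation is not given in the sources used here, and no coordinates are printed.

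The table held 45101 probe sets, of which 64 were controls. The platform annotation gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160, and probe sets without a single symbol were left unnamed. Symbols were updated through gene identifiers and the RefSeq table of mouse assembly GRCm38.p6 for 34754 probe sets, and that table also supplied the chromosome of each gene. Each of 18194 genes was represented by its brightest probe set over all 4 arrays. Genes whose mean log2 signal lay below the median of all probe sets, a signal of 60.9, were left out, which left 11749 genes; the filter does not look at the groups.

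Differences between the crosses were tested on log2 signal, with no pseudocount, by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05; limma's tests are two-sided. SE are limma's moderated standard errors, and the prior added 4.97 degrees of freedom to the 2 of the residuals. Signals are arithmetic means ± SD, whereas folds are powers of the log2 difference. Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and limma fry as alternatives, over the 39 of 40 lists with at least 3 tested members. All list p-values are adjusted over the 39 lists. Camera compares a list with all other genes, whereas fry's directional p tests whether its members move, on balance, one way. No list passed with an estimated correlation, where the 20 lists past the preset test had adjusted p from 0.453 to 0.690, and none passed fry's directional test, whose smallest adjusted p was 0.106. For the male-biased and bile acid lists the estimated correlations, -0.029 and -0.003, lay below the preset of 0.01. A higher correlation therefore does not account for the loss of these lists. The preset test's small p-values rest on the spread over genes. They do not measure the spread between the 2 mice of each cross. Fry's mixed test, which takes changes in either direction, passed 4 lists: the male-biased, female-biased and bile acid genes and the pancreatic acinar markers, with adjusted p from 0.0136 to 0.0491. Among the 6 tested acinar markers only Cela1 passed limma, over all genes or adjusted over the list alone.

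The comparison, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 genes higher and the 10 lower with the largest log2 difference among those that passed and whose arrays did not overlap, filled by smallest p where fewer passed (C6 is the one such gene), up to 4 genes of smallest p from each list described, every tested Y-linked and mitochondrially encoded gene, and Alb. Cxcl1, Gas6, Rtn4 and Cyp39a1 fall outside the rule and were named after their values were seen. Members of lists without a named probe set were left out of the tests.

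The fit was tested on simulated data of the 11749 genes in 20 runs with 200 changed genes each. With variances drawn from limma's own model, 31.4% of 2-fold and 70.1% of 4-fold changes were recovered for this comparison at a false share of 6.07%; with each gene's own fitted variance these were 57.0%, 85.2% and 10.4%. In 20 runs without any change, 34 genes were called in total and 3 of 780 list tests passed, and a list shifted by 0.8 on the log2 scale was recovered in 10 of 10 runs. The simulated genes varied independently of one another. In the data the estimated inter-gene correlation reached 0.49 for macrophage markers and 0.74 for acute-phase genes. These runs therefore cannot show how often the preset list test passes by chance when genes are correlated. The groups of 2 are too small for a test of other splits of the arrays.

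Alternatives were quantile normalization, median centring, cyclic loess, 16 added to the signal, no filter, a filter at the 75th percentile, no probe sets of suffix _x_at or _s_at, eBayes without the trend, robust eBayes, the replicate number as a block, each array left out in turn, all probe sets tested separately, a threshold of 0.1, and the other list tests. Lists without genes held by another list, and lists without their member of largest change, were added after seeing the data. No identical arrays were found, and the ratios of 3' to 5' control probe sets ran from 1.54 to 1.77 for Actb and from 0.807 to 0.909 for Gapdh.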

Results

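Liver gene expression was measured on 4 Affymetrix arrays, each hybridised with RNA from a whole liver slice of a 9-month-old male mouse raised on chow without any intervention. The mice were first-generation hybrids of the inbred strains AJ and B6 from reciprocal crosses. AB6F1 males (n = 2) had an AJ dam and a B6 sire, and B6AF1 males (n = 2) had a B6 dam and an AJ sire. Males of the reciprocal crosses carry the same mix of autosomes, but their X chromosome and mitochondria come from the other strain's dam, their Y chromosome comes from the other strain's sire, and imprinted alleles are swapped. The series concerns nonalcoholic fatty liver disease, and the one comparison its labels give asks which liver transcripts differed with the direction of the cross. Differences are given throughout as AB6F1 minus B6AF1. The labels number the mice of each cross as biological replicates. Source identifiers of the samples run in separate blocks for each cross, so that any difference in collection or handling cannot be told apart from the cross.

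Every array carried 45101 probe sets with a trimmed mean signal of 500. The median signal was 77.9 and 75.9 in AB6F1 and 72.8 and 67.2 in B6AF1, and Pearson correlations of log2 signal across genes ran from 0.961 to 0.975 over the 6 pairs of arrays. AB6F1 replicate 2 correlated with B6AF1 replicate 1 about as closely as with AB6F1 replicate 1, at 0.968 each. The replicate SD of log2 signal was 0.381 in AB6F1 and 0.351 in B6AF1. Precision was limited by the number of arrays, since 2 against 2 allows an exact permutation p no lower than 0.333 for any single gene.

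In AB6F1 males the sulfotransferases Sult2a2 and Sult3a1 and the cytochrome P450 Cyp2b13, whose transcripts are usually abundant in female mouse liver, rose, while Slco1a1 and Cyp7b1, which are usually abundant in male liver, fell. The collagen transcripts Col3a1 and Col1a2 and the acute-phase transcripts Saa2 and Socs3 also rose. Of 11749 genes tested, 25 passed limma with Benjamini-Hochberg adjustment, 16 higher and 9 lower in AB6F1. At an unadjusted p under 0.05 there were 1142 genes, 686 higher and 456 lower, where chance alone would give about 587. The arrays of the crosses did not overlap for 4841 genes, or 41.2%, against 33.3% by chance. None of the 25 genes passed when the moderated variance ignored the trend with intensity (1044 genes at an unadjusted p under 0.05), and 1 gene, Sult2a2, passed without B6AF1 replicate 1 or without B6AF1 replicate 2, against 79 genes without AB6F1 replicate 1 and 242 without AB6F1 replicate 2. Centring each array on its median gave 17 higher and 19 lower genes, so that the share of higher genes was 47.2% in place of 64%.

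Sult2a2, a hydroxysteroid sulfotransferase, showed the largest difference over all 4 arrays. Its signal was 10823 ± 4316 (SD, n = 2) in AB6F1 and 45.1 ± 28.7 (SD, n = 2) in B6AF1, a log2 difference of 8.01 ± 0.46 (SE; limma adjusted p = 0.00429). The B6AF1 signals of 24.8 and 65.4 lay near the low end of the array, so the size of the difference is uncertain: the log2 difference was 7.50 after 16 was added to every signal, and ran from 7.31 without B6AF1 replicate 1 to 8.71 without B6AF1 replicate 2. Without AB6F1 replicate 1 the log2 difference of Sult2a2 was 8.43, smaller in size than the -8.94 of Slco1a1. Sult3a1 rose from 35.6 ± 9.2 to 769 ± 331 (log2 difference 4.39 ± 0.40, limma adjusted p = 0.0111). Both B6AF1 arrays were below the expression filter's signal of 60.9 for this gene and no detection calls were used, so that no fold is given; the log2 difference was 3.87 with 16 added, and 3.94 without AB6F1 replicate 1 to 4.84 without AB6F1 replicate 2. Cyp2b13 rose 16.3-fold, from 645 ± 451 to 9501 ± 3619 (log2 difference 4.03 ± 0.49; limma adjusted p = 0.0378), with log2 differences from 3.25 without B6AF1 replicate 1 to 4.81 without B6AF1 replicate 2. Hao2, a peroxisomal hydroxyacid oxidase, rose 3.12-fold and Abcd2, a peroxisomal transporter of very long-chain fatty acids, rose 3.70-fold, with limma adjusted p of 0.00828 and 0.0262.

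These 5 genes belong to a list of 25 female-biased liver genes, of which 17 were tested. All 5 passed over all genes, 15 of the 17 were higher, and 12 passed when adjusted over the list alone, 11 higher and 1 lower. The lower one was Cyp39a1, an oxysterol hydroxylase, at -1.08 ± 0.21 (log2, SE). The median log2 difference was 1.11, and the list shifted upward against all other genes (limma camera adjusted p = 2.6e-11). With an estimated inter-gene correlation the adjusted p was 0.465.

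Male-biased liver genes moved the opposite way. All 16 tested members had negative differences, with a median of -0.76, and the list shifted downward (limma camera adjusted p = 4.4e-16; adjusted p = 0.453 with an estimated correlation). Slco1a1, an organic anion transporter of the sinusoidal membrane, fell from 5682 ± 2100 (SD, n = 2) in B6AF1 to 59.4 ± 68.1 (SD, n = 2) in AB6F1, a log2 difference of -7.30 ± 0.91 (SE; limma adjusted p = 0.0445). The AB6F1 signals were 107.5 and 11.2, the second far below the filter signal of 60.9, so the size is uncertain. The log2 difference was -6.57 with 16 added, -8.94 without AB6F1 replicate 1 and -5.67 without AB6F1 replicate 2, and the other probe set gave -5.66. Cyp7b1, the oxysterol 7-alpha-hydroxylase, fell from 16102 ± 1759 to 4351 ± 297 (log2 difference -1.89 ± 0.13; limma adjusted p = 0.00679). These were the 2 members past the test over all genes, and 9 passed when adjusted over the list alone, all lower. Complement C6, at -1.40 ± 0.18 with a limma adjusted p of 0.0506, and the fatty acid elongase Elovl3, at -2.59 ± 0.35 with a limma adjusted p of 0.061, did not pass over all genes. Slco1a1 and Cyp2b13 lost their calls under robust variance moderation (limma adjusted p = 0.349 and 0.30) and with the filter at the 75th percentile (0.0695 and 0.0627), and Slco1a1 also without probe sets of suffix _x_at and _s_at (0.0522). Both lists' mean log2 values separated the arrays of the crosses, which happens for 33.3% of values by chance. The 4 tested Y-linked genes were measured on every array and did not pass: Eif2s3y was at 0.02 ± 0.15, Kdm5d at 0.09 ± 0.21, Uba1y at 0.16 ± 0.53 and Uty at 0.63 ± 0.21. The other 2 probe sets of Uty gave -0.06 and -0.47.

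**Figure D1:**
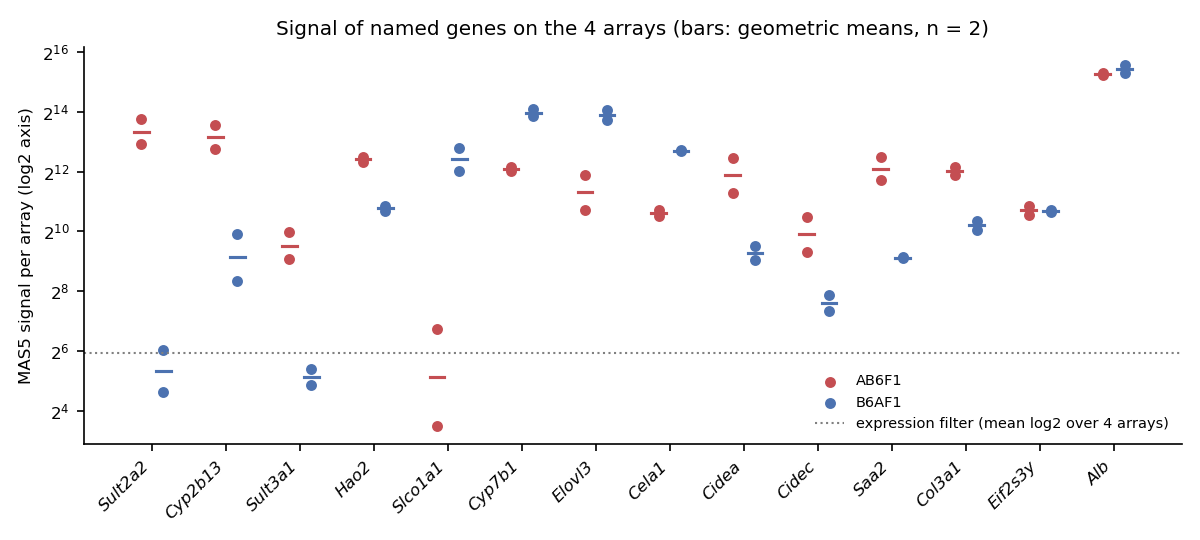
MAS5 signal of 14 named genes on each of the 4 arrays, on a log2 axis, with AB6F1 in red and B6AF1 in blue; each point is 1 array, short bars are geometric means (n = 2), and the dotted line is the filter signal of 60.9. Sult2a2 lay at 7771 and 13875 in AB6F1 and at 24.8 and 65.4 in B6AF1, whereas Eif2s3y and Alb overlapped between the crosses.

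Bile acid genes were lower on balance. The list of synthesis and transport genes had 15 tested members, of which 11 were lower and 2, the Slco1a1 and Cyp7b1 already given, passed over all genes; adjusted over the list alone, 8 were lower and 1 was higher. Its median log2 difference was -0.33 (limma camera adjusted p = 8.1e-06; adjusted p = 0.465 with an estimated correlation). Cyp27a1, the mitochondrial sterol 27-hydroxylase, was at -0.78 ± 0.11 (limma adjusted p = 0.062). Abcc4, a basolateral efflux transporter that also carries bile acids, was on the opposite side at 2.68 ± 0.39 (limma adjusted p = 0.072). The mean of the list was -0.69, and without the 3 members that other lists also hold it was -0.03 (limma camera adjusted p = 0.0265).

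Genes of lipid droplets and steatosis shifted upward without a single member passing over all genes. Of 18 tested genes, 14 were higher, 7 passed when adjusted over the list alone, and the median log2 difference was 0.54 (limma camera adjusted p = 3.7e-05; adjusted p = 0.524 with an estimated correlation). Cidea, a lipid droplet fusion protein that liver normally expresses at low level, had a signal of 4085 ± 2225 (SD, n = 2) in AB6F1 and 630 ± 150 (SD, n = 2) in B6AF1, a log2 difference of 2.60 ± 0.36 (SE; limma adjusted p = 0.062). Its relative Cidec was at 2.31 ± 0.39, the fatty acid transporter Cd36 at 0.72 ± 0.13 and the adipogenic nuclear receptor Pparg at 0.79 ± 0.17, with limma adjusted p from 0.126 to 0.208. Lipogenesis genes had a median of 0.57 over 17 tested members, 14 of them higher, and shifted upward (limma camera adjusted p = 0.0012; adjusted p = 0.679 with an estimated correlation), but no member passed over all genes or adjusted over the list alone, and the mean values of the 4 arrays overlapped between the crosses. Acaca was at 0.57 ± 0.14, Acly at 0.58 ± 0.21, Gpam at 0.57 ± 0.21 and Lpin1 at 0.61 ± 0.22. Of the 4 other probe sets of Acly, 3 were higher and 1 was lower. Without AB6F1 replicate 2 neither list passed: the lipid droplet mean went from 0.69 to 0.40 (limma camera adjusted p = 0.0879) and the lipogenesis mean from 0.40 to 0.24 (adjusted p = 0.147). The lipogenesis mean went to 0.08 without B6AF1 replicate 2, where the list also failed (adjusted p = 0.48), and to 0.72 without B6AF1 replicate 1.

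Among other lipid lists, genes of PPAR-alpha and fatty acid oxidation (22 tested, median -0.08, mean 0.09, limma camera adjusted p = 0.877), cholesterol synthesis (17 tested, median -0.07, adjusted p = 0.287) and lipoprotein export (18 tested, median -0.07, adjusted p = 0.349) did not pass. The median and the mean of the PPAR-alpha list differ in sign, and its camera test points downward with the median. One of its members rose, Vnn1, a pantetheinase, by 2.31-fold (limma adjusted p = 0.0226).

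The list for hepatic stellate cells and fibrosis shifted upward in AB6F1, with a median log2 difference of 0.77 over 23 tested genes, 20 of them higher (limma camera adjusted p = 5.1e-08; adjusted p = 0.499 with an estimated correlation). Its 2 members past the test over all genes encode fibrillar collagens: Col3a1 rose 3.50-fold, from 1186 ± 170 (SD, n = 2) to 4152 ± 537 (SD, n = 2; limma adjusted p = 0.00931), and Col1a2 rose 2.59-fold (limma adjusted p = 0.0402, or 0.052 after quantile normalization). The other probe sets of Col3a1 and Col1a2 were at 0.98 ± 0.42 and 2.15 ± 0.45. Neither passed when all probe sets were tested separately (limma adjusted p = 0.564 and 0.237). Adjusted over the list alone, 10 genes passed, all higher. Vimentin (Vim) was at 1.17 ± 0.23 and lumican (Lum) at 0.85 ± 0.18, both with limma adjusted p above 0.18.

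All 19 tested macrophage markers were higher in AB6F1, with a median of 0.87 (limma camera adjusted p = 3.5e-09; adjusted p = 0.499 with an estimated correlation). None passed over all genes and 4 passed when adjusted over the list alone. The list's array means, centred over the arrays, were 0.67 and 0.15 in AB6F1 and -0.61 and -0.20 in B6AF1. Its mean of 0.81 was 0.55 without AB6F1 replicate 1 and 1.07 without AB6F1 replicate 2. It was 0.61 without B6AF1 replicate 1 and 1.02 without B6AF1 replicate 2. Lyz2 was at 1.28 ± 0.26, Lgals3 at 1.11 ± 0.27, and the complement C1q chains C1qb and C1qa were at 1.12 ± 0.27 and 1.01 ± 0.28. Interferon response genes had a median of 0.59, with 18 of 19 higher (limma camera adjusted p = 3.0e-07, or 0.499 with an estimated correlation). The interferon mean of 0.69 was 0.48 without AB6F1 replicate 1 and 0.91 without AB6F1 replicate 2. It was 0.67 without B6AF1 replicate 1 and 0.71 without B6AF1 replicate 2. Gbp2 was at 1.60 ± 0.26 and the chemokine Cxcl10 at 1.65 ± 0.43. The AB6F1 signals of Cxcl10 were unlike, 248.5 and 607.9 against 113.3 and 135.2 in B6AF1. Antigen presentation genes had a median of 0.11, with 13 of 15 higher (limma camera adjusted p = 0.0043; adjusted p = 0.689 with an estimated correlation), and the MHC class II genes H2-Aa, H2-Eb1 and Cd74 were at 1.28 ± 0.27, 1.34 ± 0.31 and 1.29 ± 0.30. The mean of that list was 0.42. It was 0.16 without AB6F1 replicate 1 and 0.38 without B6AF1 replicate 1, where the list failed (limma camera adjusted p = 0.259 and 0.0754), and 0.68 without AB6F1 replicate 2.

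Acute-phase genes shifted upward with a median of only 0.11 over 21 tested genes and a mean of 0.77 (limma camera adjusted p = 0.0011; adjusted p = 0.690 with an estimated correlation). Saa2, serum amyloid A2, rose 7.88-fold, from 558 ± 12.2 (SD, n = 2) to 4562 ± 1731 (SD, n = 2; limma adjusted p = 0.00828), and Socs3, a feedback inhibitor of cytokine signalling, rose 3.24-fold (limma adjusted p = 0.0262). Saa1 was at 2.23 ± 0.41 and Orm3 at 1.89 ± 0.37, and 7 genes passed when adjusted over the list alone, all higher. The AB6F1 signals of Saa1 were unlike, 20005 and 7701 against 2182 and 3186 in B6AF1. Saa2 and Socs3 were read by probe sets of suffix _x_at, which can bind related transcripts. On the remaining probe set Socs3 was at 1.04 ± 0.34 and did not pass (limma adjusted p = 0.420). The list failed without AB6F1 replicate 1, where its mean was 0.43 (limma camera adjusted p = 0.109), and without B6AF1 replicate 1, where it was 0.61 (adjusted p = 0.110).

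**Figure D2:**
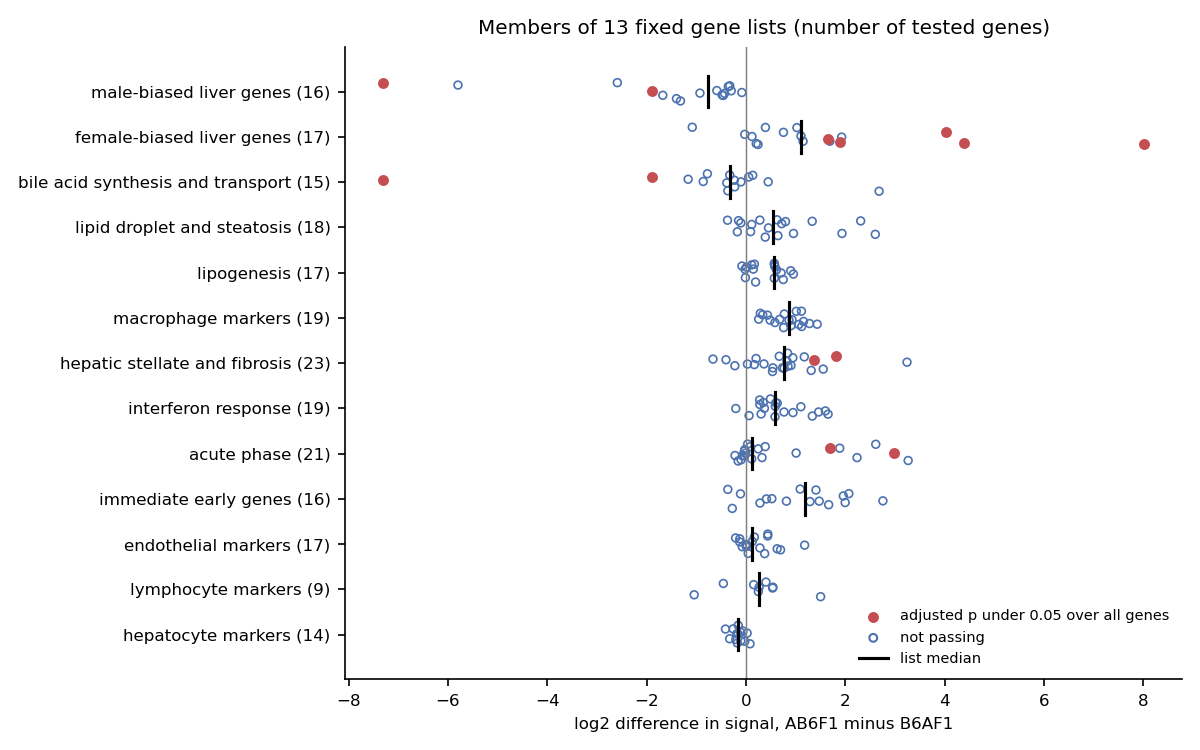
Log2 difference in signal (AB6F1 minus B6AF1, horizontal axis) of the tested members of 13 gene lists, 1 row per list with its number of genes; filled red points passed limma's adjusted p over all genes, open blue points did not, and black bars are list medians. Macrophage markers all lay above 0 with a median of 0.87, male-biased genes all lay below 0 with a median of -0.76, and endothelial markers had a median of 0.13.

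Markers of cell types were set beside these groups because whole liver was used. Hepatocyte markers were slightly lower, with a median of -0.16 and 12 of 14 negative (limma camera adjusted p = 0.006; adjusted p = 0.679 with an estimated correlation), and albumin (Alb) was at -0.16 ± 0.13. The hepatocyte shift failed after quantile normalization (limma camera adjusted p = 0.225), after cyclic loess (0.540), without probe sets of suffix _x_at and _s_at (0.0834), and without AB6F1 replicate 2 (0.205) or B6AF1 replicate 2 (0.136), where its mean of -0.15 became -0.10. Endothelial markers (17 tested, median 0.13, limma camera adjusted p = 0.147), lymphocyte markers (9 tested, median 0.26, adjusted p = 0.394), cholangiocyte and progenitor markers (8 tested, median 0.32, adjusted p = 0.147), neutrophil markers (7 tested, median 0.65, adjusted p = 0.0531), erythroid markers (4 tested, median 0.05, adjusted p = 0.630), adipocyte markers (5 tested, median 0.05, adjusted p = 0.266) and skeletal muscle markers (3 tested, median 0.53, adjusted p = 0.365) did not pass. Pancreatic acinar markers did not pass as a list either (6 tested, median 0.17, mean -0.01, camera test downward, adjusted p = 0.702), and their median and mean differ in sign. The exception among them was Cela1, an elastase, which fell from 6690 ± 164 (SD, n = 2) in B6AF1 to 1567 ± 153 (SD, n = 2) in AB6F1, a log2 difference of -2.10 ± 0.13 (SE; limma adjusted p = 0.00429), while the other 5 acinar genes were higher.

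Hepatocyte genes of both lobule zones were lower on balance. Pericentral genes had a median of -0.27, with 12 of 16 negative (limma camera adjusted p = 0.0013), and periportal genes had a median of -0.23, with 11 of 13 negative (limma camera adjusted p = 0.002). The adjusted p was 0.499 for each with an estimated correlation. Cyp1a2, a pericentral P450 of the xenobiotic list, fell 2.02-fold (limma adjusted p = 0.0262). Gulo was at -0.67 ± 0.12 and Lgr5 at -0.61 ± 0.20, and of the periportal genes the urea cycle enzymes Asl and Cps1 were at -0.63 ± 0.20 and -0.33 ± 0.12, and Igf1 at -0.32 ± 0.11. Etnppl was at -1.60 ± 0.70, with unlike AB6F1 signals of 1040 and 6244 against 8365 and 7105 in B6AF1. Xenobiotic metabolism genes had a median of -0.12 over 19 tested (limma camera adjusted p = 0.0036; adjusted p = 0.499 with an estimated correlation), with array means that overlapped between the crosses; Ces2a was at -0.84 ± 0.14, Gstm6 at -0.47 ± 0.16 and Nr1i3 at -0.41 ± 0.15. The pericentral list failed without AB6F1 replicate 2 (limma camera adjusted p = 0.0818) and without genes that another list holds (0.123), and its mean ran from -0.31 without AB6F1 replicate 1 to -0.09 without AB6F1 replicate 2. The periportal and xenobiotic lists failed after cyclic loess (0.0619 and 0.0618) and without AB6F1 replicate 1 (0.101 and 0.318). The periportal mean was -0.11 without AB6F1 replicate 1 and -0.49 without AB6F1 replicate 2, against -0.30 in full. The xenobiotic mean turned from -0.17 to 0.05 without AB6F1 replicate 1, and was -0.39 without AB6F1 replicate 2, -0.08 without B6AF1 replicate 1 and -0.26 without B6AF1 replicate 2.

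The other genes with a large change had no common list. Rad51b, a homologous recombination factor, rose 7.31-fold from 113 ± 7.6 to 827 ± 50.7 (SD, n = 2 each; limma adjusted p = 0.00734), on 1 probe set. Gsn, the actin-severing protein gelsolin, rose 4.02-fold and Rcan2, a regulator of calcineurin, rose 3.61-fold, each with a limma adjusted p of 0.00931; the 4 other probe sets of Gsn and the other of Rcan2 were higher as well. Susd4 fell 5.51-fold, Sult5a1 fell 4.09-fold and the organic anion transporter Slc22a7 fell 3.16-fold, all with a limma adjusted p of 0.00828. Igfbp2, a binding protein of insulin-like growth factors, fell 4.07-fold (limma adjusted p = 0.0239) and the P450 Cyp4f14 fell 2.31-fold (limma adjusted p = 0.0318). The remaining 3 genes, taken up after their values were seen, were Cxcl1, a neutrophil chemokine, which rose 2.83-fold, Gas6, a ligand of TAM receptors, which rose 2.79-fold, and Rtn4, a reticulon, which rose 2.15-fold, with limma adjusted p of 0.0299, 0.0239 and 0.0215. On the probe set left without suffixes _x_at and _s_at, Cxcl1 was at 1.89 ± 0.29 and did not pass (limma adjusted p = 0.0884).

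Immediate early genes had a median log2 difference of 1.19, with 13 of 16 higher and 8 past the test when adjusted over the list alone (limma camera adjusted p = 1.7e-06; adjusted p = 0.499 with an estimated correlation). Fos was at 2.76 ± 0.42, Btg2 at 2.0 ± 0.28, Gadd45g at 1.66 ± 0.42 and Jun at 1.41 ± 0.32, and none passed over all genes. Unfolded protein response genes had a median of 0.15, with 14 of 18 higher (limma camera adjusted p = 0.0011; adjusted p = 0.499 with an estimated correlation); Creld2 was at 0.91 ± 0.13 and Manf at 0.59 ± 0.13. Genes of liver tumours and fetal liver had a median of 1.18 over 10 tested, with 8 higher (limma camera adjusted p = 4.2e-04; adjusted p = 0.499 with an estimated correlation); Ly6d was at 2.86 ± 0.47, Scd2 at 1.21 ± 0.27 and Gpc3 at 1.53 ± 0.50. Lcn2 was at 3.26 ± 0.83, with unlike AB6F1 signals of 6539 and 1107 against 158 and 497 in B6AF1. Ly6d also had unlike AB6F1 signals, 320.6 and 899.5 against 75.1 and 72.9 in B6AF1. Cell cycle genes had a median of 0.68, with 13 of 15 higher (limma camera adjusted p = 0.0021; adjusted p = 0.524 with an estimated correlation), and Ccnd1 was at 0.72 ± 0.15; the list failed without AB6F1 replicate 2 (0.243) and without B6AF1 replicate 2 (0.0752), where its mean of 0.65 became 0.41 and 0.38. Genes of NRF2 and glutathione stress had a median of 0.15, with 13 of 17 higher (limma camera adjusted p = 0.0461, or 0.499 with an estimated correlation). The metallothionein Mt2 was at 2.75 ± 0.71 (signals of 5413 and 1632 in AB6F1 and 228 and 863 in B6AF1). Mt1 was at 2.14 ± 0.80 (12834 and 3226 in AB6F1 and 684 and 3109 in B6AF1) and Hmox1 at 1.03 ± 0.30. The NRF2 list failed in 6 settings: with median centring (limma camera adjusted p = 0.0717), without the intensity trend (0.166), without probe sets of suffix _x_at and _s_at (0.259), without its member of largest change (0.122), without AB6F1 replicate 2 (0.162) and without B6AF1 replicate 2 (0.0933).

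Nuclear-encoded oxidative phosphorylation genes were lower by a small amount, with a median of -0.08 and 26 of 32 negative (limma camera adjusted p = 0.017; adjusted p = 0.499 with an estimated correlation). No member passed in any count, Ndufb5 was at -0.24 ± 0.11, and its other probe set was at 0.13. The mean of that list turned to 0.02 after cyclic loess. The list failed after quantile normalization (mean -0.005, limma camera adjusted p = 0.897), with the filter at the 75th percentile (0.0894), and without AB6F1 replicate 1 (0.0961), AB6F1 replicate 2 (0.0737) or B6AF1 replicate 2 (0.109). Genes of gluconeogenesis and glycogen (16 tested, median -0.13, limma camera adjusted p = 0.0531) and heat shock genes (12 tested, median 0.13, adjusted p = 0.546) did not pass.

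Chromosomes and imprinted genes, which the cross direction sets, showed no list-wide shift in 1 direction. Camera's test cannot show changes that go up in some members and down in others. Fry's mixed test, which takes either direction, gave adjusted p of 0.0531 for chromosome X. For the maternally and paternally expressed imprinted lists it gave 0.485 and 0.153. The 341 tested genes of chromosome X had a median of 0.01, with 176 higher and 165 lower, and none passed over all genes (limma camera adjusted p = 0.557). At an unadjusted p under 0.05, 25 X-linked genes were higher and 7 lower. The Y-linked list had a median of 0.12 over its 4 genes (limma camera adjusted p = 0.349), and the 5 tested genes of chromosome Y had a median of 0.09 (adjusted p = 0.394). Imprinted genes expressed from the maternal allele had a median of -0.08 over 12 tested (adjusted p = 0.175), and those expressed from the paternal allele a median of 0.13 over 12 tested (adjusted p = 0.790). ND5, the one mitochondrially encoded gene tested, was at -0.09 ± 0.14.

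The circadian clock list did not shift as a whole (16 tested, median 0.10, limma camera adjusted p = 0.521), but its members lay on both sides of 0. Dbp, whose transcript peaks late in the light period, was at 2.15 ± 0.40 and Usp2, of a similar phase, at 1.26 ± 0.35, while Nfil3, of the opposite phase, was at -1.45 ± 0.30. Bhlhe40, which was put in neither phase group, was at 1.32 ± 0.21. None passed over all genes, and adjusted over the list alone 3 were higher and 1 was lower. The mean values of the clock list and of the immediate early list separated the arrays of the crosses, which happens for 33.3% of values by chance. The clock mean averages genes of opposite phase, so nothing is drawn from its separation.

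**Figure D3:**
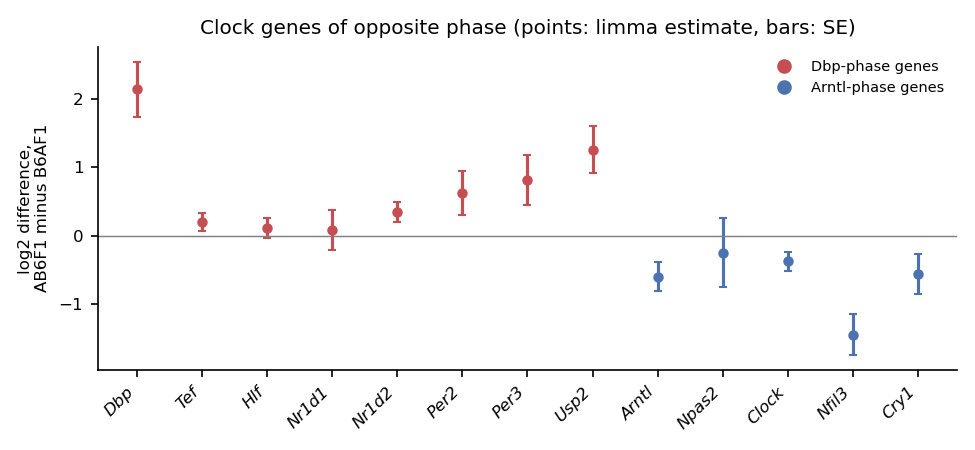
Log2 difference in signal (AB6F1 minus B6AF1, vertical axis) of 13 clock genes, with points as limma estimates and bars as SE. Red genes were grouped with Dbp and blue genes with Arntl, and genes of a group need not peak together. The 8 red estimates lay above 0, from 0.09 ± 0.29 for Nr1d1 and 0.11 ± 0.14 for Hlf, both within their SE of 0, to 2.15 for Dbp, and the 5 blue estimates lay below 0, with Nfil3 at -1.45.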

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

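Lists without genes held by another list and lists without their member of largest change were settings chosen after the data were seen. The count of 25 genes (16 higher, 9 lower) stayed within 1.5 times under quantile normalization (24), median centring (36), cyclic loess (28), 16 added to the signal (26), no filter (26), the 75th percentile filter (21), no _x_at and _s_at probe sets (21) and robust eBayes (32). All probe sets tested separately gave 36 probe sets, 20 higher and 16 lower, which stand for 26 genes and 4 probe sets without a single gene. The lower genes alone came to 19 with median centring and 14 with robust eBayes. A threshold of 0.1 gave 46 genes, 27 higher and 19 lower. eBayes without the trend gave 0 genes (0 higher, 0 lower) with 1044 at an unadjusted p under 0.05; the cause was not tested. Leaving out an array in turn gave 1 to 242 genes, 1 to 142 higher and 0 to 100 lower: 79 without AB6F1 replicate 1, 242 without AB6F1 replicate 2, and 1 without either B6AF1 replicate, where the lone array of a cross is assumed to vary like the pair of the other. All 25 genes were among the 79 and the 242, and Sult2a2 was the 1. The cause was not tested. With 2 arrays per cross, dim signals limit the fold of Sult2a2, Sult3a1 and Slco1a1. No call for any named gene turned in direction.

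The 20 lists past camera became 16 to 21 in each other setting, except 0 with an estimated correlation and 0 with fry. Of the lists that passed, 13 of 17 without AB6F1 replicate 2, 15 of 17 without AB6F1 replicate 1, 18 of 20 without B6AF1 replicate 1 and 15 of 16 without B6AF1 replicate 2 were among the 20, as were 19 of 20 with median centring, 20 of 21 without a filter, 20 of 21 with the replicate block and 19 of 20 without the largest member; in the other settings all were. The replicate block, which pairs mice by number, gave 62 genes, 40 higher and 22 lower, among them all 25. It also gave 21 lists, among them all 20. Across genes, the difference between replicates 1 and 2 in AB6F1 correlated at -0.027 with that in B6AF1. This single value cannot show whether same-numbered mice shared a processing step. Male-biased, female-biased, bile acid, macrophage, stellate and fibrosis, interferon, immediate early and unfolded protein response lists were past the threshold in all 16 other settings, and the tumour and fetal list in all 15 that tested it. Of the called lists, oxidative phosphorylation turned, with a mean of 0.020 after cyclic loess, and the mean but not the camera direction of xenobiotic metabolism turned, from -0.17 to 0.047 without AB6F1 replicate 1; the cause was not tested. All other reversals were of genes and lists that had not passed, given here as log2 values, and their cause was not tested. A list counts as reversed where camera's direction turns, which need not be the sign of its mean. The PPAR-alpha mean was 0.129 with quantile normalization, 0.142 with cyclic loess, 0.056 with the 75th percentile filter, and 0.094 with both the replicate block and fry. Lipoprotein export was at 0.033 with quantile normalization and 0.055 with cyclic loess. The paternally expressed imprinted list was at -0.055 with 16 added, 0.039 without a filter, -0.013 with the 75th percentile filter, 0.0079 without _x_at and _s_at probe sets and 0.067 without its largest member. Pancreatic acinar markers were at -0.0053 without the trend and 0.413 without their largest member, and erythroid markers at -0.138 without theirs. With arrays left out in turn, means ran from -0.021 to 0.209 for PPAR-alpha, -0.334 to 0.195 for cholesterol synthesis, -0.245 to 0.122 for gluconeogenesis, -0.094 to 0.343 for heat shock, 0.136 to 0.235 for the clock list, 0.022 to 0.431 for endothelial, -0.041 to 0.330 for erythroid, -0.111 to 0.10 for acinar markers and -0.366 to 0.040 for maternally expressed imprinted genes; cholesterol synthesis passed upward without AB6F1 replicate 2 (adjusted p = 0.0129). ND5 was at 0.0034 with quantile normalization, 0.036 with cyclic loess, and -0.241 to 0.068 with arrays left out. Eif2s3y was at -0.042 with median centring and -0.130 to 0.180 with arrays left out, and Kdm5d at -0.099 to 0.275. Mcm5 was at -0.310 without _x_at and _s_at probe sets, which reads another probe set.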

Other observations

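The tests in this part that were chosen only after the result was seen are those of Y-linked genes, of hepatocyte share, of RNA degradation and of the heat shock list; the tests of STAT5 genes, clock genes and the X chromosome were set before. When all 22519 probe sets were tested separately, limma with Benjamini-Hochberg adjustment called 36, of which 20 were higher and 16 lower. Among these, 4 had no single gene symbol here and so entered no gene list, with log2 differences of -2.89, -1.41, 1.52 and -1.55.

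Male-biased liver genes were lower and female-biased genes higher in AB6F1 males. A female liver under a male label is argued against by the 4 Y-linked genes, whose mean in the lowest AB6F1 array lay 0.0756 above the B6AF1 mean on the log2 scale. A lower share of hepatocytes would lower both lists, but the female-biased median was 1.11, with 15 of 17 genes higher. Lower growth hormone and STAT5 signalling is a candidate explanation that the data do not settle. The 6 STAT5-dependent genes measured had a median of -0.136. Igf1, Igfals and Ghr were lower, at -0.32 ± 0.11, -0.29 ± 0.13 and -0.29 ± 0.11 (log2, SE). Cish, Onecut1 and Socs2 were higher but imprecise, at 1.19 ± 0.66, 0.46 ± 0.64 and 0.02 ± 0.46. The 95% bootstrap interval, which resamples the 6 genes with equal weight and not mice, ran from -0.308 to 0.825. The parents' strains and the mother's environment stay open and untested.

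Macrophage and stellate or fibrosis genes were higher in AB6F1. If a lower share of hepatocytes raised every other cell type alike, the other types would rise as much, but the 42 macrophage and stellate genes exceeded the 38 endothelial, lymphocyte, cholangiocyte and erythroid genes by 0.597 in median log2 difference, and by 0.551 once neutrophil, adipocyte, muscle and acinar genes were added to these. In array means this excess, centred over the arrays, was 0.351 and 0.213 in AB6F1 and -0.20 and -0.365 in B6AF1, a gap wider than the ranges within each cross. When this test was set, the macrophage and stellate lists were known to have passed and the 4 types not to have. Some excess was therefore built in, and it cannot decide whether the hepatocyte share was lower. Genes of one type are not independent, and neutrophil markers alone, with a median of 0.65, lay only 0.144 below. Skeletal muscle markers, with 3 tested, had a median of 0.53. RNA degradation is argued against by control probe sets whose 3' to 5' ratios differed by at most 1.15 times between arrays. More macrophage and stellate cells, or more of these transcripts per cell, may be present in AB6F1 livers; that was not tested, and batch of collection cannot be told apart from cross.

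Immediate early genes were higher in AB6F1. A different time of day at collection is a candidate explanation. In median log2 difference, 8 clock genes grouped with Dbp and 5 grouped with Arntl moved apart by 1.049 (medians 0.489 and -0.56, exact permutation p = 0.0155, 95% bootstrap interval 0.533 to 2.08). Both the p and the interval come from reshuffling or resampling genes of 1 clock, which are not independent. They do not measure the spread between mice. Handling stress that also induces heat shock genes is argued against by a heat shock median of 0.132. The interval over genes, not mice, ran from -0.007 to 0.242, and with arrays left out the list mean ran from -0.094 to 0.343. Handling stress without such induction was not tested and stays open. Whether time of day also moved the metabolic lists was not tested, and an effect of the cross on the clock itself stays open.

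The X chromosome showed no excess of differences: 9.38% of 341 X-linked and 9.73% of 11360 autosomal genes had an unadjusted p under 0.05 (odds ratio 0.961, 95% interval 0.642 to 1.39, Fisher's exact p = 0.926). If AJ alleles bound the probes less, X-linked genes would tend to be lower in AB6F1, but 21.9% of the X-linked genes at that threshold were lower against 40.5% of autosomal ones (Fisher's exact p = 0.0427).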
